A study of Mus musculus with 28 samples.

How the data were processed

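RNA was measured in the frontal cortex of 28 male C57Bl/6 mice, 1 library per mouse. Per the labels' protocols, 1 hemisphere of each brain was kept in RNAlater before the frontal cortex was dissected, total RNA was extracted on a Maxwell RSC instrument, its integrity was scored as a RIN, and libraries were made with the TruSeq Stranded Total RNA kit after ribosomal RNA depletion with Ribo-Zero Gold. The 4 groups were 8 mice under chronic social stress (CSS) with 8 controls of 21 weeks, and 6 mice with induced type 2 diabetes (T2D) with 6 controls of 30 or 31 weeks. Each group came from the treatment label and the title of its sample. The labels describe the samples as separate mice, so the spread between libraries of a group includes the difference between animals.

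The authors deposited 1 table of estimated counts per gene for each cohort, whose values were not whole numbers and summed to a different total in each library. Per the submitters' processing notes, the tools included Salmon 1.1.0, which assigns reads to transcripts, and the genome build was mm10. How transcripts were summed to genes, whether the values were scaled for transcript length, whether strand was used and how low genes were removed are not given in the sources used here. Every gene in the CSS table reached at least 1.00908 CPM (counts of a gene per M counts of the listed total) in 8 libraries, and in that of T2D at least 1.01332 CPM in 6 libraries, so genes below about 1 CPM had been left out before deposit. There were 15097 genes in the CSS table and 15054 in that of T2D, of which 14888 were in both. In each of them 17 genes lay on scaffolds outside the chromosomes, and 39 and 41 identifiers shared a symbol with another; they were kept apart. Gene symbols, Ensembl identifiers and biotypes came from the tables. Coordinates, transcript lengths and exon overlaps came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, in which 99.7% of the identifiers of each table were found.

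Totals of the listed genes lay between 12.1 and 37.5 M per library. Before any test the values were rounded to whole numbers. Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Genes were filtered with edgeR's default filter, which removed none of the listed genes, and library sizes were scaled by TMM. Each cohort was tested by itself with edgeR's robust quasi-likelihood test, stressed or diabetic against control, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All adjusted p-values of single genes are from this test unless another tool is named. A further contrast over all 28 libraries and the 14888 shared genes took the CSS change minus the T2D change, in which a difference between the cohorts cancels. Levels are given as CPM with the SD over libraries, and fold changes as log2 values from edgeR with their standard errors. For each gene the treated libraries on the side of its change were counted relative to the mean of the controls.

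The tests of genes and gene lists and the genes to be named were fixed before the data were examined, while tests of library values and list scores and the mixed form of fry were not. For each cohort the rule took, among genes past the threshold with a mean log2 CPM of at least 1 and a symbol that is not a predicted model, the 12 largest rises and the 12 largest falls. It also took the 5 genes of smallest p, the 3 members of smallest p of each gene list, and 22 fixed genes of stress hormone, insulin, neuronal, glial and blood function, and allowed members of summarised lists to be left out. For the contrast between cohorts it took the 5 genes of smallest p in each direction. Where a count of 5 or fewer members of a list passed, the remaining members were named too. Further members were also named among the mitochondrially encoded and the ribosomal protein genes, where more passed. All of these were chosen after their values were seen.

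A total of 38 gene lists of cell types, neighbouring brain regions, blood, RNA quality and pathways were tested with limma's camera on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested genes. Each list was also tested with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance, and in its mixed form whether they move either way. A list's score in a library was the mean of its members' log2 CPM with a prior count of 2, relative to the mean of the cohort's controls. Scores and library values (total, RIN, shares of counts, slope on transcript length, principal components) were compared between groups by two-sided exact permutation tests. Adjustment was over 18 comparisons of library values and over the lists of a cohort. The slope was that of log2 level, relative to each gene's mean over the cohort's libraries, on log2 transcript length.

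The size of the response without a threshold was the square root of the mean over genes of the squared log2 fold change less its squared standard error, called the effect spread below, and its error came from leaving out each library in turn. To set the cohorts side by side at the same number of libraries, 50 random draws of 6 CSS and 6 control libraries were tested. The correlation of the fold changes of both cohorts was compared with 100 permutations of the labels within the cohorts. The levels of the CSS groups at the called genes were set beside those of the T2D groups on log2 CPM scaled over all 28 libraries, a comparison chosen after seeing the data. For each count of genes or lists, 100 splits of the same libraries into groups of the same sizes were drawn, the real one included.

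The test was checked on simulated counts with the means, library sizes and dispersions of the real libraries, 200 changed genes and a shift of 0.3 log2 units in the immediate early genes. It recovered 38.8%, 80.6% and 95.5% of genes changed by 1.25, 1.5 and 2 times in the CSS design of 15097 genes, with 5 false calls among 150. In the T2D design of 15054 genes it recovered 8.96%, 58.2% and 81.5%, with 8 false calls among 106. In the contrast between cohorts over 14888 genes it recovered 7.46%, 35.8% and 69.7%, with 2 false calls among 77. The shifted list was called in each of the 3 designs and no other list was. Counts of each gene were drawn independently, without the correlation that genes of a list have in the real libraries. The simulation therefore cannot show how often lists are falsely called there.

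Alternatives fixed before the data were examined were size factors in place of TMM (edgeR's RLE), no filter, a filter of 1 CPM in as many libraries as the smaller group, RIN as a covariate, 1 surrogate variable from sva, the replicate number as a block, DESeq2, limma voom with sample quality weights, all 4 groups in 1 fit, and each library left out in turn. Chosen after seeing the data were mixed fry, the removal of each library's trend on transcript length by a spline of 4 degrees of freedom, the marker scores of striatum and thalamus as covariates, the number after C in the title codes of the CSS cohort as a factor, subsets of its controls by that number and a test between them, and the omission of 2 libraries of a cohort. No libraries were found to be copies of one another. No column of the tables was left unused. Values of a few single genes that these rules would name are not reported here. Estimated counts were used as they stand, so genes that share sequence with close copies, such as mitochondrial genes with nuclear copies and pseudogenes, and genes that overlap others are less certain than single-copy genes.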

Results

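RNA was sequenced from the frontal cortex of 28 male C57Bl/6 mice, with 1 library per mouse. The series set social against metabolic stress, each in a cohort with its own controls. In the first cohort, 8 mice had lived alone for 7 weeks and met other mice in confrontations on each of the last 20 days (chronic social stress, CSS). The other 8 mice were controls, and all were 21 weeks old. In the second, 6 mice had been given 75 mg/kg streptozotocin, a toxin of the insulin-producing beta cells, and 21 weeks of a diet with 43.2% of its energy as fat (a model of type 2 diabetes, T2D). Their 6 controls were likewise 30 or 31 weeks old. Totals of the listed genes were 15.2 to 21.9 M estimated counts in CSS and 14.3 to 37.5 M in its controls. They were 14.3 to 22.7 M in T2D and 12.1 to 21.6 M in its controls. The RNA integrity number (RIN) was 9.63 ± 0.341 in CSS and 9.53 ± 0.225 in its controls (SD, n = 8 each), and 9.05 ± 0.235 in T2D and 9.37 ± 0.509 in its controls (SD, n = 6 each). It did not pass a two-sided exact permutation test in either cohort (p = 0.548 and 0.225, adjusted p = 0.822 and 0.450 over 18 comparisons of library values).

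The comparison of CSS with its controls asked which genes of the frontal cortex differed between stressed and control mice. A total of 683 of 15097 genes did, 318 higher and 365 lower, mostly by small amounts, with a median change of 1.23-fold. The count depended on the libraries, with 222 to 794 when 1 was left out. It also depended on the controls, with 0 to 1130 calls and a median of 12.5 over the 70 choices of 4 of the 8. Against CSS_control 5 to 8 alone edgeR called 0 genes (1971 at an unadjusted p under 0.05), as in 27 of the 70 choices. The median log2 change of the 683 genes was 0.24 against these 4 controls, beside 0.30 against all 8. These choices of controls were made after seeing the data. They kept 4 of the 8 controls, and fewer libraries alone can lower the count. Col1a1, a chain of type I collagen, rose 2.20-fold, from 4.26 ± 0.859 to 9.31 ± 3.60 CPM, and Per2, a core repressor of the circadian clock, rose 1.76-fold, from 29.0 ± 2.51 to 51.0 ± 16.1 CPM (SD, n = 8 each). Among genes that fell, Ncl, which encodes the nucleolar protein nucleolin, went from 208 ± 18.4 to 152 ± 17.3 CPM, and C1qa, a complement subunit made by microglia, from 35.9 ± 2.69 to 26.2 ± 5.44 CPM. With a preset correlation between genes, markers of microglia as a group were lower and markers of meningeal fibroblasts higher, and neither list passed with an estimated correlation (adjusted p = 0.589 for both).

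Of the 683 genes, 627 were protein-coding, 74 differed by more than 1.5-fold and 13 by more than 2-fold. At an unadjusted p under 0.05 there were 3245 genes, beside 755 expected from chance, and the smallest adjusted p was 0.00545. The library values of both groups did not overlap in 92 genes, beside 2.35 expected from chance.

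**Figure D1:**
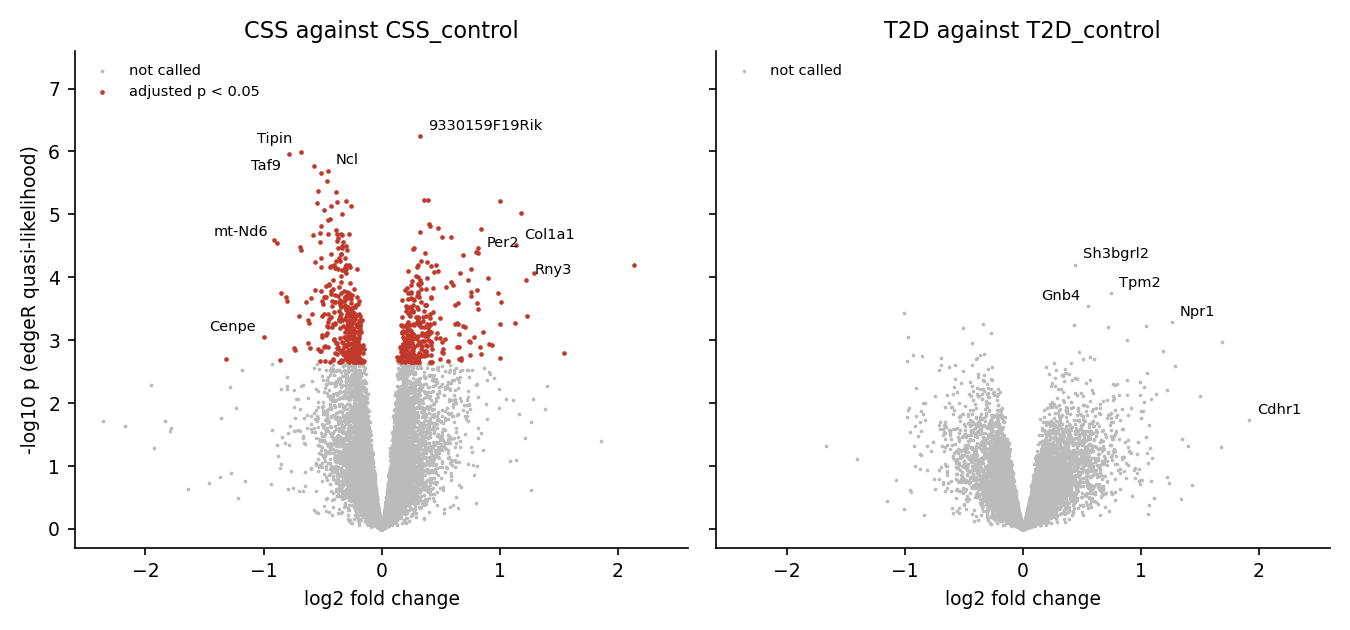
Each point is a gene, with its log2 fold change against controls on the horizontal axis and −log10 of the unadjusted p of edgeR's quasi-likelihood test on the vertical axis, for CSS on the left and T2D on the right. Coloured points are the 683 genes with an adjusted p under 0.05 in CSS, and T2D had 0.

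The 5 genes of smallest p moved in the same direction in 8 of 8 CSS libraries, with no overlap between the groups. 9330159F19Rik (ENSMUSG00000004360, chromosome 10, 29211606 to 29230779, GRCm38/mm10), a gene of no established function, rose by 0.33 ± 0.05 log2 units (SE), from 82.6 ± 2.89 to 104 ± 6.70 CPM (adjusted p = 0.00545). Tipin (ENSMUSG00000032397, chromosome 9, 64281581 to 64305424), a partner of Timeless at replication forks, fell by 0.68 ± 0.10, from 13.9 ± 2.15 to 8.67 ± 1.03 CPM (adjusted p = 0.00545). Taf9 (ENSMUSG00000052293, chromosome 13, 100651579 to 100656060), a subunit of the transcription factor TFIID, fell by 0.78 ± 0.11, from 14.4 ± 2.34 to 8.38 ± 1.38 CPM (adjusted p = 0.00545). Its value is uncertain, because 73.8% of its exon bases were shared with Ak6 on the same strand. Cetn3 (ENSMUSG00000021537, chromosome 13, 81783077 to 81797155), a centrin of the centrosome, fell by 0.57, from 50.7 ± 7.26 to 34.2 ± 3.61 CPM (adjusted p = 0.00555). Ncl (ENSMUSG00000026234, chromosome 1, 86344719 to 86359400) fell by 0.46 ± 0.07 (adjusted p = 0.00555). Exons of Cetn3 overlapped the opposite-strand gene Gm17259 in 8.67% of their bases and those of 9330159F19Rik overlapped Gm49353 in 6.88%. These 5 genes kept their call in each of the 16 fits that left out 1 library.

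The 12 largest rises and falls named next were taken among called genes with a mean log2 CPM of at least 1 that are not predicted gene models. Outside these limits the predicted gene Gm10719, named after its value was seen, had the largest rise of all called genes (log2 2.14, adjusted p = 0.0126). Among the 12 rises, the small Y RNA Rny3 (ENSMUSG00000064945, chromosome 6, 47781624 to 47781725) went from 12.7 ± 4.0 to 29.5 ± 11.1 CPM (log2 1.22 ± 0.24, adjusted p = 0.0160). The guide RNA Scarna6 of the Cajal body rose from 2.54 ± 0.572 to 5.75 ± 1.89 CPM (adjusted p = 0.00753). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) rose by 1.14 ± 0.21 log2 units in 8 of 8 CSS libraries (adjusted p = 0.00999). Kdm6b, a demethylase of histone H3, rose from 7.62 ± 1.43 to 13.5 ± 3.61 CPM (log2 0.82 ± 0.15, adjusted p = 0.00999), and Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) rose by 0.82 ± 0.15 in 7 of 8 CSS libraries (adjusted p = 0.0106). The other rises were Rin3, a Rab5 exchange factor (log2 1.01), Rny1 (1.005), the matrix protein Adamtsl3 (0.91), the transcription factor Bach2 (0.86), the basement membrane collagen Col4a6 (0.84), Scarna10 (0.84) and the lipid droplet protein Plin4 (0.82). Their adjusted p lay between 0.0203 and 0.0445. Scarna10 shared 72.9% of its exon bases with Ncapd2 on the same strand and is uncertain.

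The 12 falls began with the pseudogene Rps12-ps3 (log2 −1.32, adjusted p = 0.0476), a copy of the ribosomal protein gene Rps12, which itself rose (0.38, adjusted p = 0.0322), so reads may have been divided between them. mt-Nd6 (MT, 13552 to 14070), the complex I subunit on the light strand of mitochondrial DNA, fell by 0.89 ± 0.16, from 56.7 ± 10.1 to 30.7 ± 8.85 CPM (adjusted p = 0.00970). Cenpe, a kinetochore motor, fell by 0.99, the endothelial receptor gene Ecscr by 0.91, the fructose transporter gene Slc2a5 by 0.86. The myosin gene Myh7b fell by 0.81, Yjefn3 by 0.80, the pseudogene Morf4l1-ps1 by 0.74, the immune receptor gene Havcr2 by 0.68 and the transcription factor gene Tfap4 by 0.62. Their adjusted p lay between 0.00967 and 0.0481. Taf9 and Tipin completed these 12. The gene body of Yjefn3 overlaps that of Ndufa13 on the same strand. Of these 24 genes, 14 kept their call in each of the 16 fits that left out 1 library. The other 10 (Rny1, Adamtsl3, Bach2, Col4a6, Scarna10, Rps12-ps3, Cenpe, Slc2a5, Morf4l1-ps1 and Tfap4) lost it in 6 to 13 of these fits, with a largest adjusted p of 0.0974.

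**Figure D2:**
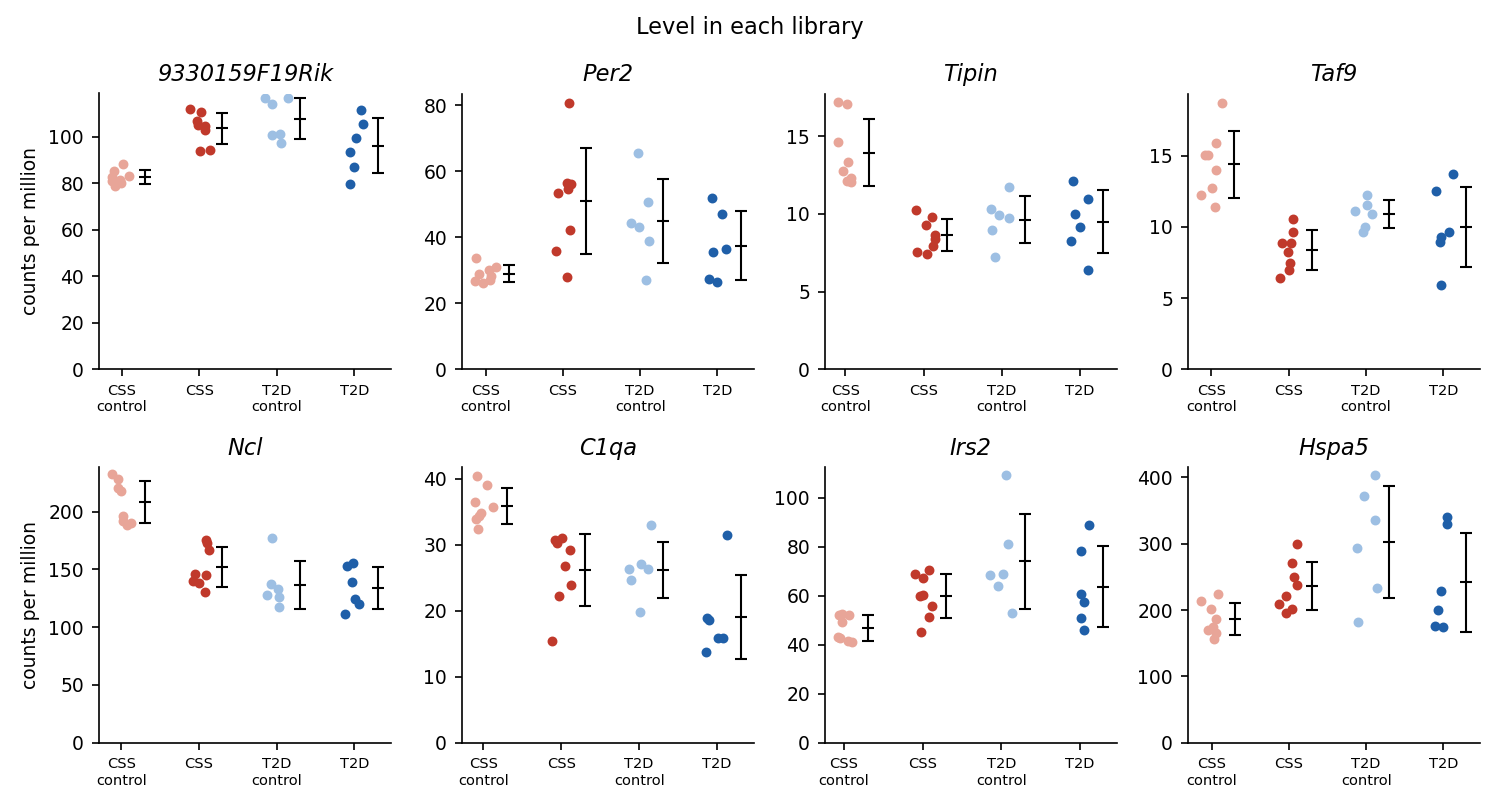
Level in CPM of 8 named genes in the 4 groups. Each coloured point is a library, the horizontal black mark its group's mean and the bar the SD over 8 libraries in CSS and its controls and 6 in T2D and its controls.

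Markers of microglia, the resident macrophages of the brain, were the list with the smallest p in CSS. Of 17 markers 5 fell, none rose and 12 did not pass (10 lower when adjusted over the list alone). Their median log2 change was −0.35 (camera adjusted p = 1.66e-07, adjusted p = 0.589 with an estimated correlation). C1qa fell by 0.45 (adjusted p = 0.0274), the cathepsin gene Ctss by 0.49 (0.0394), the receptor gene Csf1r by 0.23 (0.0433), C1qb by 0.39 (0.0437) and C1qc by 0.38 (0.0448). The mean marker level was −0.34 ± 0.35 log2 units relative to controls and below their mean in 8 of 8 CSS libraries (exact p = 0.00280, adjusted p = 0.101 over the lists). Single calls were less firm, since C1qa lost its call without CSS 6 or CSS_control 2 (adjusted p at most 0.0619) and the other 4 in 10 to 12 of the 16 fits (at most 0.0929). Csf1r overlapped Hmgxb3 on the opposite strand in 15.1% of its exon bases.

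Markers of meningeal fibroblasts, cells of the membranes over the cortex, were higher in CSS. All 16 had a positive fold change, and 1 of them (Col1a1) passed over all genes and 6 when adjusted over the list alone. Their median was 0.49 (camera adjusted p = 3.96e-05, adjusted p = 0.589 with an estimated correlation). Lum, a proteoglycan of collagen fibrils, had a log2 fold change of 0.76 (adjusted p = 0.0574). The extracellular matrix and collagen list, which also holds Col1a1, was higher too, with 1 of 26 members past the test over all genes and 1 when adjusted over the list alone. Its median was 0.14 (camera adjusted p = 0.00560, adjusted p = 0.589 with an estimated correlation). Endothelial markers had a median of 0.12 (camera adjusted p = 0.0316, adjusted p = 0.628 with an estimated correlation). Of 17 members 2 were higher (3 when adjusted over the list alone), the lipid transporter gene Mfsd2a (0.35, adjusted p = 0.0330) and the anion transporter gene Slco1a4 (0.24, adjusted p = 0.0331). None of 6 red blood cell genes passed over all genes, while adjusted over the list alone 5 were higher and 1 lower. Their median was 0.77 (camera adjusted p = 0.0429, adjusted p = 0.589 with an estimated correlation), with Hbb-bt, a beta globin gene, at 0.92 (adjusted p = 0.0623) and Alas2, the heme synthesis gene of red cells, at 0.90 (adjusted p = 0.0692). The endothelial call ended without CSS 6 (adjusted p = 0.0812), CSS 7 (0.0746), CSS 8 (0.0777), CSS_control 1 (0.0687) or CSS_control 4 (0.0828), and with 1 surrogate variable (0.0509). The red blood cell call ended without CSS 3 (0.0672), CSS 5 (0.0548), CSS 7 (0.0612), CSS_control 1 (0.0687), CSS_control 2 (0.0524) or CSS_control 3 (0.0511), with 1 surrogate variable (0.0632) or without both CSS 5 and CSS_control 5 (0.0703).

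No other cell type list passed in CSS. Oligodendrocyte precursor markers had 2 of 13 higher (5 when adjusted over the list alone) and did not pass as a list (median 0.11, camera adjusted p = 0.0512). The 2 were Gpr17, a receptor of cells that are becoming oligodendrocytes (0.40, adjusted p = 0.00903), and the matrix gene Tnr (0.22, adjusted p = 0.0459). Of 18 astrocyte markers 2 rose (3 when adjusted over the list alone), the glutamate transporter gene Slc1a2 (0.22, adjusted p = 0.0393) and the growth factor receptor gene Fgfr3 (0.23, adjusted p = 0.0488). The list's median was 0.12 (camera adjusted p = 0.0833). Gfap did not pass (0.20, adjusted p = 0.348). Of 19 inhibitory neuron markers 2 fell, and also 2 when adjusted over the list alone, the neuropeptide genes Npy (−0.46 in 7 of 8 CSS libraries, adjusted p = 0.0243) and Sst (−0.30, adjusted p = 0.0279). Their list had a median of −0.09 (camera adjusted p = 0.168). Of 17 excitatory neuron markers 1 rose, Rasgrf2 (0.22, adjusted p = 0.0331), and also 1 when adjusted over the list alone, with a median of −0.00 (camera adjusted p = 0.782). None of 19 oligodendrocyte and myelin markers passed over all genes (1 higher and 1 lower when adjusted over the list alone; median −0.05, camera adjusted p = 0.103). The same was true of 14 pericyte and smooth muscle markers (2 higher when adjusted over the list alone; median 0.18, camera adjusted p = 0.0922) and of 6 ependymal markers (median −0.01, mean 0.04, test upward, camera adjusted p = 0.795). Choroid plexus markers and blood leukocyte genes had 4 and 1 members in the table, too few to test.

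Markers of neighbouring regions were tested for differences in dissection. The 19 striatal projection neuron markers were lower in CSS as a list, with no member past the test over all genes (median −0.23, camera adjusted p = 0.00870, adjusted p = 0.675 with an estimated correlation). That call ended without CSS 3 (adjusted p = 0.0624), CSS_control 2 (0.0835) or CSS_control 7 (0.0556). The lists of olfactory bulb neurons (11 genes, median −0.18, camera adjusted p = 0.374) and of thalamus and hypothalamus (8 genes, median 0.24, camera adjusted p = 0.247) did not pass. With the striatal and thalamic scores as covariates, an alternative chosen after seeing the data, 310 genes were called in CSS, 290 of them among the 683.

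With the preset correlation, genes of neuronal activity, of the clock and of mitochondrial DNA were also called as lists. Their scores did not pass the exact permutation test over libraries (adjusted p = 0.315, 0.199 and 0.299). The activity genes had a score above the control mean in 4 of 8 CSS libraries. The 26 immediate early genes, which neurons transcribe within minutes of activity, had a median of 0.22 (camera adjusted p = 0.00870, adjusted p = 0.628 with an estimated correlation), while no member passed over all genes or adjusted over the list alone. Nr4a3 was at 0.68 (adjusted p = 0.0574), Homer1 at 0.34 (0.0782), Arc at 0.63 (0.307) and Fos at 0.29 (0.547). Of 19 circadian clock genes 2 rose (3 when adjusted over the list alone), Per2 and the kinase gene Csnk1d (0.25, adjusted p = 0.0218), which phosphorylates PER proteins. The clock list's median was 0.11 (camera adjusted p = 0.0140, adjusted p = 0.589 with an estimated correlation), and its call ended without CSS_control 5 (adjusted p = 0.0534) or without both CSS 5 and CSS_control 5 (0.122). Of 13 mitochondrially encoded protein genes 6 fell and none rose (8 lower and 1 higher when adjusted over the list alone). Their median was −0.40 and their mean −0.12, with a camera adjusted p of 0.00868 (adjusted p = 0.589 with an estimated correlation). Besides mt-Nd6 these were mt-Atp8 (−0.51, adjusted p = 0.0126), mt-Cytb (−0.43, 0.0193), mt-Nd1 (−0.42, 0.0203), mt-Nd4 (−0.46, 0.0284) and mt-Co1 (−0.20, 0.0318). Of these, mt-Nd1, mt-Nd4 and mt-Co1 were named after their values were seen. mt-Atp8 shares 21.1% of its exon bases with mt-Atp6, and mt-Nd6 2.70% with the opposite-strand mt-Nd5. The share of all counts from mitochondrial DNA was 6.84 ± 0.906% in CSS and 7.61 ± 0.645% in controls (exact p = 0.0637, adjusted p = 0.233).

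Interferon-stimulated genes and MHC class I were lower as a list, with 2 of 23 lower, and 2 when adjusted over the list alone (median −0.13, camera adjusted p = 0.0103, adjusted p = 0.589 with an estimated correlation). These were B2m, the light chain of MHC class I (−0.38, adjusted p = 0.00970), and the heavy chain gene H2-K1 (−0.33, adjusted p = 0.0492), and the list's call ended without CSS_control 6 (adjusted p = 0.0661). Of 26 genes of heat shock and the unfolded protein response 5 rose (8 higher and 2 lower when adjusted over the list alone) and the list did not pass (median 0.09, camera adjusted p = 0.0922). They were the chaperone genes Dnajb1 (0.37, adjusted p = 0.0213), Hspa5 (0.34, 0.0411; 187 ± 24.3 to 236 ± 36.1 CPM) and Hspb1 (0.52, 0.0437), the transcription factor gene Xbp1 (0.27, 0.0420) and Creld2 (0.31, 0.0459). Of 32 genes of insulin and IGF signalling 4 rose (7 higher and 2 lower when adjusted over the list alone), and this list did not pass either (median 0.05, camera adjusted p = 0.115). They were the adaptor gene Irs2 (0.36, adjusted p = 0.0287; 46.8 ± 5.18 to 59.9 ± 8.83 CPM), the receptor genes Igf1r (0.26, 0.0378) and Igf2r (0.17, 0.0466), and Rptor (0.20, 0.0497), a subunit of the kinase complex mTORC1. In the 16 fits that left out 1 library, Dnajb1 lost its call in 1, Hspa5 in 10, Xbp1 in 11, Creld2 in 12 and Hspb1 in 13. Irs2 lost its call in 5 of these fits, Igf1r in 9, Igf2r in 13 and Rptor in 14. Where 4 or 5 members of the lists of this paragraph are named, the ones beyond the 3 of smallest p were chosen after their values were seen.

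Of 74 nuclear-encoded genes of the respiratory chain and ATP synthase 5 fell (5 lower and 1 higher when adjusted over the list alone; median −0.01, camera adjusted p = 0.354). They were Ndufa10 (−0.34, adjusted p = 0.00999), Cox6b1 (−0.35, 0.0202), Ndufa12 (−0.31, 0.0259), Ndufa13 (−0.20, 0.0380) and Ndufa5 (−0.33, 0.0447). Of 78 cytosolic ribosomal protein genes 2 rose and 4 fell (8 and 10 when adjusted over the list alone; median 0.02, test downward, camera adjusted p = 0.958). Among the falls were Rps26 (−0.37, adjusted p = 0.00915), Rpl21 (−0.27, 0.0226) and Rpl23 (−0.27, 0.0331), and the rises Rps12 and Rpl27 (0.41, 0.0365). The named genes have pseudogene copies that can share their reads. Of 21 glucocorticoid-responsive genes Plin4 rose and Mt1, a metallothionein gene, fell (−0.30, adjusted p = 0.0102; 1 higher and 2 lower when adjusted over the list alone), with a median of −0.02 (camera adjusted p = 0.510). Of 22 stress axis and neuropeptide genes 2 fell, Npy and Sst, and the same number when adjusted over the list alone (median −0.08, camera adjusted p = 0.289). Of 20 glycolysis genes Gapdh fell (−0.18, adjusted p = 0.0249; 1 higher and 1 lower when adjusted over the list alone; median −0.01, camera adjusted p = 0.383). Of 14 genes of inflammatory cytokines and NF-kB targets the adhesion molecule gene Vcam1 rose (0.31, adjusted p = 0.0485; 1 when adjusted over the list alone; median 0.14, camera adjusted p = 0.121). Of 14 nuclear-retained long non-coding RNAs Snhg14 rose (0.33, adjusted p = 0.0169; 2 higher and 1 lower when adjusted over the list alone; median 0.04, camera adjusted p = 0.327).

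Of 24 genes of synaptic vesicle release Rab3a fell (−0.21, adjusted p = 0.0196; 1 when adjusted over the list alone; median −0.03, camera adjusted p = 0.318). The table held a further entry of Rab3a on a scaffold outside the chromosomes, which rose (0.67, adjusted p = 0.0476), and the sum of both was 299.9 ± 10.8 CPM in controls and 272 ± 15.01 CPM in CSS. No member of the remaining 7 lists passed over all genes in CSS. Their medians were 0.06 for postsynaptic scaffolds (camera adjusted p = 0.0922), −0.04 for GABA receptors (0.318), 0.12 for neurotrophins and growth factors (0.327). They were 0.04 for glutamate receptors (0.355), −0.03 for cholesterol synthesis (0.490), 0.02 for fatty acid oxidation and ketone use (0.527) and 0.02 for monoamine and acetylcholine receptors (0.795, test downward).

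In all, 10 of 36 lists were called in CSS with the preset correlation, 6 higher and 4 lower. With an estimated correlation none was (smallest adjusted p = 0.589), and fry called none either (smallest adjusted p = 0.0971). No list's score passed the exact permutation test over libraries (smallest adjusted p = 0.101). The mixed form of fry, which asks whether genes of a list move in any direction and was not fixed in advance, called 14 lists in CSS, and 0 in T2D and in CSS minus T2D. Microglia and meningeal fibroblast markers kept their call in each of the 16 fits that left out 1 library. So did immediate early genes, mitochondrially encoded proteins and the extracellular matrix and collagen list. Of the 22 genes fixed for stress hormone, insulin, neuronal, glial and blood function, 21 were in the CSS table and Sst alone passed. The glucocorticoid targets Fkbp5 (0.01, adjusted p = 0.972), Sgk1 (−0.27, 0.127) and Tsc22d3 (0.14, 0.20), the glucocorticoid receptor gene Nr3c1 (0.08, 0.636), Crh (−0.09, 0.802) and Bdnf (0.27, 0.264) did not pass.

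**Figure D3:**
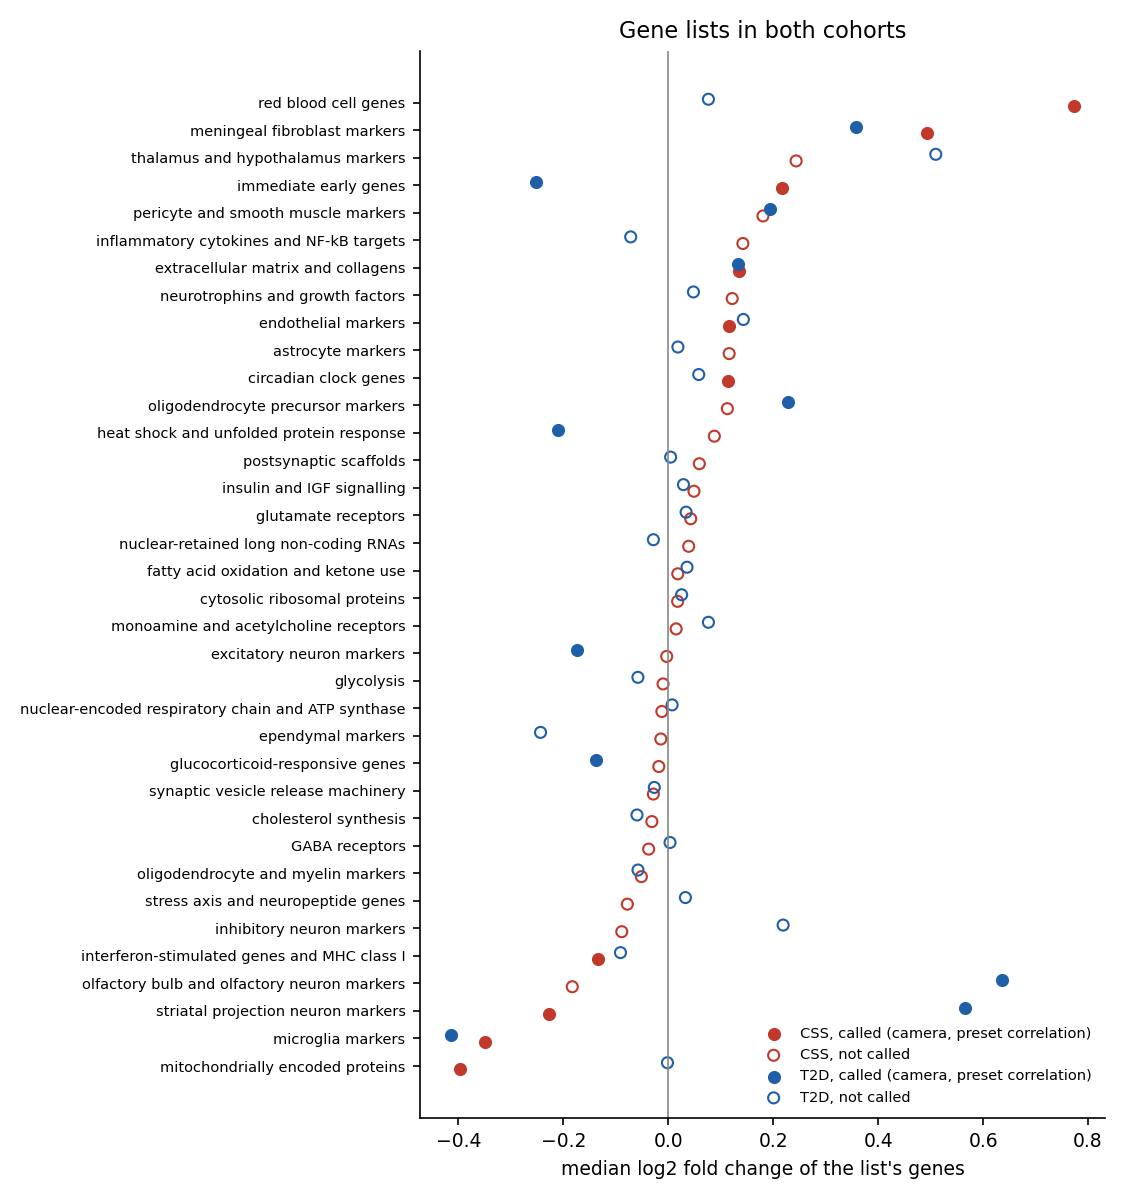
Median log2 fold change over the tested genes of each list in CSS (red) and T2D (blue), each against its controls. Filled points are lists called by camera with a preset correlation, 10 in CSS and 11 in T2D, and none of them was called with an estimated correlation.

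Calls in CSS went with transcript length. Genes that rose had a median longest transcript of 5444 bp, genes that fell 2452 bp and the others 3414 bp. Across genes, which are not independent replicates, fold change and length had a Spearman correlation of 0.24 (0.07 in T2D). A slope on doubling of length was fitted in each library to log2 level relative to each gene's mean over the cohort. It was 0.0184 ± 0.0303 in CSS libraries and −0.0184 ± 0.0176 in controls. On this scale the means of groups of equal size mirror each other, so only their difference of 0.0368 has meaning (exact permutation p = 7.77e-04, adjusted p = 0.00839). CSS 5 had a slope of 0.0907 and the other CSS libraries −0.00577 to 0.0200. Without CSS 5 and CSS_control 5, a subset chosen after seeing the data, the correlation of fold change with length was 0.14. With each library's length trend removed, an alternative chosen after seeing the data, 349 genes were called, of which 313 were among the 683. Of these 349, 125 were higher (35.8%, beside 46.6% before) and the others lower. With all 4 groups in 1 fit, 506 genes were called, 186 higher and 320 lower.

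**Figure D4:**
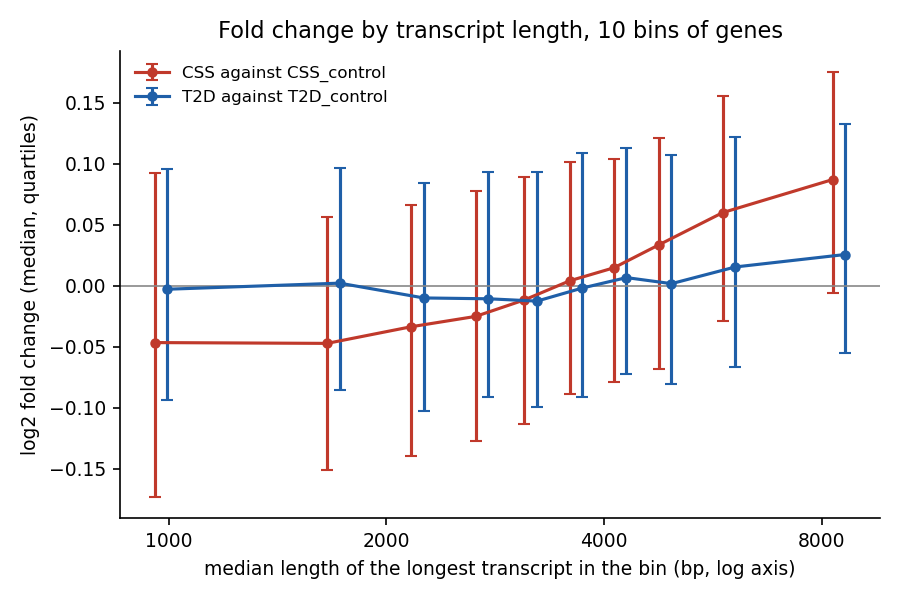
Median log2 fold change (points) with quartiles (bars) of 10 bins of genes by length of their longest transcript, on a log axis in bp, for CSS and T2D. In CSS the medians ran from −0.05 in the shortest bin to 0.09 in the longest.

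The number of CSS calls also varied with the libraries. The fits that left out 1 library gave 222 to 794 calls, with 360 without CSS 5, 222 without CSS 6, 439 without CSS 8, and 276, 251, 402, 429 and 414 without CSS_control 1 to 5. There were 232 without both CSS 5 and CSS_control 5. Of 76 genes named for a call in CSS, not counting Gm10719, 29 kept their call in each of the 16 fits and 47 lost it in 1 to 14, with a largest adjusted p of 0.108. Title codes of the controls carry a number after the letter C, whose meaning the labels do not give. It is 1 in CSS_control 1 to 4, 2 in CSS_control 5 to 7 and 3 in CSS_control 8. Against the 4 controls of number 1 alone, a subset chosen after seeing the data, 1130 genes were called, and against the other 4 edgeR called 0, with 1971 at an unadjusted p under 0.05. All 683 genes kept their direction against either subset, with a median log2 change of 0.35 against the former and 0.24 against the latter. These genes were called against all of the same controls, so their direction was largely fixed in advance and is no independent support. In CSS the number is 1 in CSS 1, 2 in CSS 2, 3 in CSS 3 to 5 and 4 in CSS 6 to 8. A fit with this number as a factor took equal numbers in both groups as 1 level, which the labels do not state. No control has number 4, so CSS 6 to 8 did not add to the estimated stress effect, and lost information alone could end calls. In this fit 2 genes were called, Spred1 (0.36 without the factor, adjusted p = 0.00660) and Dnajb5 (0.47, adjusted p = 0.0322), both named because they were these 2.

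The comparison of T2D with its controls asked the same of metabolic stress. No gene of 15054 passed the test. With the preset correlation markers of microglia were lower as a list and markers of striatal neurons higher, but neither passed with an estimated correlation (adjusted p = 0.796 for both), and the striatal test turned downward with 1 surrogate variable (adjusted p = 0.790). The gene of smallest p was Sh3bgrl2, an SH3-binding protein gene, at 29.3 ± 2.52 CPM in controls and 39.7 ± 3.58 CPM in T2D (SD, n = 6 each), and the complement gene C1qb had a log2 fold change of −0.54. The insulin receptor gene Insr (0.14), the glucose transporter gene Slc2a1 (−0.09), Igf1 (0.10), Fkbp5 (−0.05), Sgk1 (−0.06), Gfap (0.30) and Bdnf (−0.57) did not pass, nor did any other of the 22 fixed genes. All single-gene tests in T2D had an adjusted p of at least 0.825.

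With edgeR, 0 genes were called in T2D and 879 had an unadjusted p under 0.05, beside 753 expected from chance. DESeq2 called 4, limma voom with sample quality weights 0 (2163 at an unadjusted p under 0.05), and edgeR 0 in each fit that left out 1 library. The groups did not overlap in 22 genes, beside 32.6 expected from chance. The 5 genes of smallest p, none of which passed, differed in the same direction in 6 of 6 T2D libraries. Besides Sh3bgrl2 (ENSMUSG00000032261, chromosome 9, 83548327 to 83638801, log2 0.44 ± 0.08) they were the beta-tropomyosin gene Tpm2 (ENSMUSG00000028464, chromosome 4, 43514711 to 43523765), at 3.74 ± 0.654 CPM in controls and 6.26 ± 0.827 CPM in T2D, and the G protein subunit gene Gnb4 (ENSMUSG00000027669, chromosome 3, 32580332 to 32616585), at 35.5 ± 4.96 and 52.1 ± 8.97 CPM. The others were Arhgap25 (ENSMUSG00000030047, chromosome 6, 87458545 to 87533259), at 16.1 ± 3.25 and 7.95 ± 2.86 CPM, and the natriuretic peptide receptor gene Npr1 (ENSMUSG00000027931, chromosome 3, 90450591 to 90465866), at 1.48 ± 0.508 and 3.59 ± 1.33 CPM. DESeq2 called Gnb4, Tpm2 and Sh3bgrl2 higher and Arhgap25 lower.

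Marker lists in T2D shifted for microglia and for neurons of neighbouring regions. No single gene of any list passed over all genes. All 17 microglia markers had a negative fold change (median −0.41, camera adjusted p = 2.01e-06, adjusted p = 0.796 with an estimated correlation), with C1qb at −0.54, Csf1r at −0.50 and C1qc at −0.45. Their mean level was −0.38 ± 0.34 log2 units and below the control mean in 5 of 6 T2D libraries (exact p = 0.0671). All 19 striatal projection neuron markers had a positive fold change (median 0.57, camera adjusted p = 2.93e-05, adjusted p = 0.796 with an estimated correlation), with the transcription factor genes Isl1 at 1.096 and Six3 at 0.83. With 1 surrogate variable the median was 0.21 and the test turned downward (adjusted p = 0.790). Their mean level in single T2D libraries ranged from −1.40 in T2D 4 to 1.24. Olfactory bulb markers had a median of 0.64 (2 higher when adjusted over the list alone; camera adjusted p = 0.00253, adjusted p = 0.796 with an estimated correlation), led by the cadherin gene Cdhr1 at 3.55 ± 1.43 CPM in controls and 13.1 ± 18.3 CPM in T2D. That call ended without T2D 3 (median 0.24, adjusted p = 0.0995) or with 1 surrogate variable (median 0.06, adjusted p = 0.205). Excitatory neuron markers were lower (median −0.17, camera adjusted p = 0.00180, adjusted p = 0.796 with an estimated correlation), among them Neurod6 (−0.68), Fezf2 (−0.61) and Nptx1 (−0.38), until T2D 3 was left out (adjusted p = 0.109) or 1 surrogate variable was added (median 0.01, adjusted p = 0.9998).

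**Figure D5:**
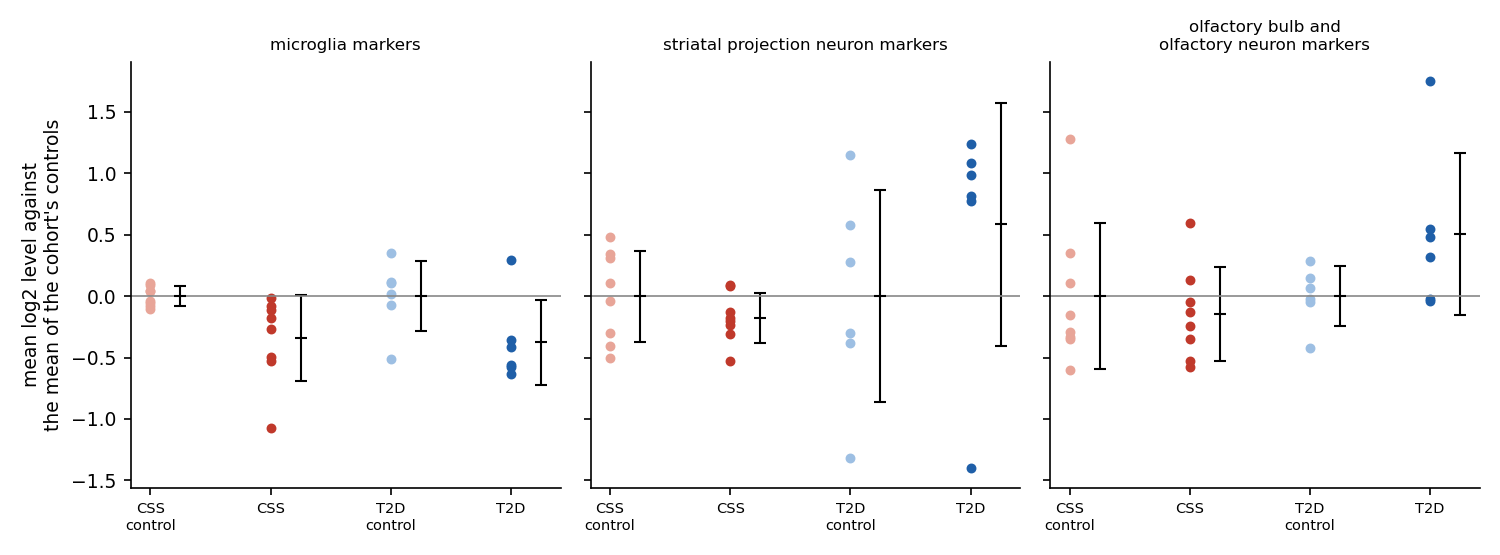
Mean log2 level of microglia, striatal and olfactory markers in each library (points), relative to the mean of the cohort's controls, with group mean (mark) and SD (bar), for 8 CSS, 8 CSS_control, 6 T2D and 6 T2D_control libraries. T2D 4 had the lowest striatal value, −1.40, and T2D 3 the highest olfactory value, 1.75.

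Vascular and membrane markers in T2D depended on single libraries. Pericyte and smooth muscle markers (median 0.19, 2 higher when adjusted over the list alone, camera adjusted p = 0.00558) and meningeal fibroblast markers (median 0.36, camera adjusted p = 0.00253) were higher, each with adjusted p = 0.796 with an estimated correlation. Without T2D 4 neither list passed (adjusted p = 0.104 and 0.130). The collagen-binding proteoglycan gene Dcn was at a log2 fold change of 1.08, with 36.9 CPM in T2D 4 and 4.27 to 7.15 CPM in the other T2D libraries. Extracellular matrix and collagen genes (median 0.13, camera adjusted p = 0.0240, adjusted p = 0.796 with an estimated correlation) lost their call without T2D 2 (0.0585), T2D 3 (0.0588), T2D 4 (0.336), T2D_control 4 (0.145) or T2D_control 5 (0.0502), or with 1 surrogate variable (0.269). Oligodendrocyte precursor markers (median 0.23, camera adjusted p = 0.0334, adjusted p = 0.796 with an estimated correlation) lost theirs without T2D 3 (0.109), T2D 4 (0.110), T2D_control 1 (0.0855), T2D_control 4 (0.153) or T2D_control 6 (0.0647). They also lost it with RIN as a covariate (0.0832) or 1 surrogate variable (median −0.02, adjusted p = 0.642). Without both T2D 3 and T2D 4, a subset chosen after seeing the data, the lists of precursors (0.318), pericytes (0.259), fibroblasts (0.604), extracellular matrix (0.672) and excitatory neurons (0.362) did not pass.

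Stress response lists were lower in T2D with the preset correlation, but their scores did not pass the exact permutation test over libraries (adjusted p = 0.724 for each). Genes of heat shock and the unfolded protein response had a median of −0.21 (camera adjusted p = 8.61e-06, adjusted p = 0.796 with an estimated correlation), with the endoplasmic reticulum genes Herpud1 at −0.31 and Pdia3 at −0.20 and the transcription factor gene Atf4 at −0.27. With RIN as a covariate the median was −0.06 and the call was lost (adjusted p = 0.0672). Glucocorticoid-responsive genes had a median of −0.14 (1 lower when adjusted over the list alone; camera adjusted p = 0.00973, adjusted p = 0.796 with an estimated correlation), with Zbtb16 at −0.54, Fam107a at −0.51 and Tsc22d3 at −0.35. The call ended with RIN as a covariate (adjusted p = 0.354), without T2D 2 (0.0719) or without T2D_control 6 (0.198). Immediate early genes had a median of −0.25 (camera adjusted p = 0.0126, adjusted p = 0.870 with an estimated correlation), although Nr4a2 was at 0.51 and Jun at 0.36. With RIN as a covariate their median was 0.00 (adjusted p = 0.697), and the call also ended with 1 surrogate variable (0.396) or without T2D 1 (0.0537), T2D 2 (0.102), T2D 5 (0.109), T2D_control 5 (0.0886) or T2D_control 6 (0.601).

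The other 26 lists did not pass in T2D. Inhibitory neuron markers had a median of 0.22, with 1 higher when adjusted over the list alone. Thalamus and hypothalamus markers had a median of 0.51 (camera adjusted p = 0.0773 for both lists). Synaptic vesicle release was at −0.03 (0.0773). Synpr (0.42) and Trh (1.50) are members of the olfactory bulb list given above and of neither neuron list named here. Medians were −0.06 for glycolysis (0.139), −0.06 for cholesterol synthesis (0.169), 0.14 for endothelial markers (0.209), −0.09 for interferon-stimulated genes and MHC class I (0.237), −0.24 for ependymal markers (0.239). They were 0.50 for the 5 choroid plexus markers (0.245), 0.04 for fatty acid oxidation and ketone use (0.245), 0.03 for ribosomal proteins (0.352), −0.07 for inflammatory cytokines (0.357), 0.01 for the nuclear-encoded respiratory chain (0.452). The medians of nuclear-retained long non-coding RNAs (−0.03, 0.473), oligodendrocytes (−0.06, 0.541), clock genes (0.06, 0.544) and glutamate receptors (0.03, 0.544) were near 0. They were −0.00 for mitochondrially encoded proteins (mean 0.08, 0.618), 0.08 for monoamine and acetylcholine receptors (0.642), 0.02 for astrocytes (0.642), 0.08 for red blood cell genes (0.739). Further medians were 0.00 for postsynaptic scaffolds (mean −0.00, test downward, 0.739), 0.00 for GABA receptors (mean 0.03, test downward, 0.761). The last were 0.03 for the stress axis and neuropeptides (0.848), 0.03 for insulin and IGF signalling (0.848) and 0.05 for neurotrophins and growth factors (0.935). Blood leukocyte genes had 1 member in the table. In all, 11 of 37 lists were called, 6 higher and 5 lower, none with an estimated correlation (smallest adjusted p = 0.796) or with fry (smallest adjusted p = 0.902). No list's score passed the exact permutation test over T2D libraries (smallest adjusted p = 0.724).

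The cohorts were then compared with each other, since a call in CSS and none in T2D is not itself a difference. In 12 of 14888 genes the CSS change differed from the T2D change, 7 with a higher and 5 with a lower value in CSS, all at an adjusted p of 0.0485. 9330159F19Rik was at a log2 fold change of 0.33 in CSS and −0.17 in T2D, a difference of 0.49, and Spred1, an inhibitor of Ras-MAPK signalling, at 0.36 and −0.25 (difference 0.60). The small nucleolar RNA Snora74a was at 0.62 and −0.51 (1.12), the synaptic adhesion gene Igsf9b at 0.38 and −0.40 (0.77) and the cadherin gene Cdh19 at 0.38 and −0.35 (0.72). Dnajc3, a chaperone gene of the endoplasmic reticulum (0.28 and −0.27, difference 0.54), and Sgsm1 (0.42 and −0.21, difference 0.63) were the others of the 7 and were named after their values were seen. Among the genes lower in CSS minus T2D were C2cd2l (−0.37 and 0.12, difference −0.50), the actin regulator gene Coro1b (−0.30 and 0.10, −0.40), Sh3bgrl2 (−0.10 and 0.44, −0.55) and the receptor gene Gpr12 (−0.30 and 0.44, −0.74). All exon bases of Snora74a lie in Snhg4, so its value is uncertain.

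At an unadjusted p under 0.05 the contrast gave 1840 genes, beside 744 expected from chance. The 12 calls were close to the threshold, and leaving out 1 library gave 0 to 32 calls. Of the 28 such fits 19 gave 0 calls. The others gave 2 without CSS 2, 12 without CSS 4, 15 without CSS 7, 21 without CSS_control 6, 10 without CSS_control 8, 7 without T2D 3, 32 without T2D 6, 6 without T2D_control 2 and 31 without T2D_control 3. With RIN as a covariate, with 1 surrogate variable or with the length trend removed edgeR called 0 genes (1469, 1729 and 1786 at an unadjusted p under 0.05), while DESeq2 called 130 and limma voom with sample quality weights 45.

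Of 36 lists 7 differed between the cohorts with the preset correlation, and none with an estimated correlation (smallest adjusted p = 0.969) or with fry (smallest adjusted p = 0.404). Striatal markers were lower in CSS minus T2D (median −0.78, camera adjusted p = 1.38e-05), as were olfactory bulb markers (−0.84, 0.0309), inhibitory neuron markers (−0.33, 0.0332; 1 lower when adjusted over the list alone) and mitochondrially encoded proteins (−0.40, 0.0104; 6 lower when adjusted over the list alone). Heat shock and the unfolded protein response (0.27, 9.84e-05; 9 higher when adjusted over the list alone), immediate early genes (0.45, 8.53e-04; 1 higher when adjusted over the list alone) and excitatory neuron markers (0.14, 0.0449) were higher. For each of the 7 the adjusted p was 0.969 with an estimated correlation. Microglia markers, called lower in each cohort with the preset correlation alone (adjusted p = 0.589 in CSS and 0.796 in T2D with an estimated one), had no call in this test (median 0.03, test downward, camera adjusted p = 0.876). The striatal and heat shock calls held in each of the 28 fits that left out 1 library. With 1 surrogate variable the striatal call ended (median −0.44, adjusted p = 0.435), as did those of the olfactory bulb (−0.27, 0.174), inhibitory neuron (−0.11, 0.174), mitochondrial (−0.33, 0.0609) and excitatory neuron lists (−0.04, 0.950). With RIN as a covariate that of the immediate early genes ended (median 0.19, adjusted p = 0.171). The olfactory bulb list did not pass without CSS_control 4 (median −0.42, adjusted p = 0.0843), T2D 3 (−0.39, 0.234) or T2D_control 6 (−0.71, 0.0559). The inhibitory neuron list did not pass without CSS_control 4 (0.0843), T2D 3 (0.130), T2D 6 (0.0511), T2D_control 1 (0.0823), T2D_control 2 (0.0599) or T2D_control 6 (0.0559). The mitochondrial list did not pass without T2D 1 (0.109), T2D 3 (0.0623) or T2D_control 6 (0.0559), and the immediate early genes without T2D_control 6 (0.0559). Excitatory neuron markers lost their call in 16 of these fits, most of all without T2D 3 (0.478).

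Across the 14888 genes in both tables, which are not independent replicates, the log2 fold changes of the cohorts had a Spearman correlation of 0.05 (permutation p = 0.733 over 100 permutations of the labels) and a Pearson correlation of 0.05. Of the 682 CSS calls listed in the T2D table, 385 (56.5%) had the same direction there (permutation p = 0.614). In T2D 45 had an unadjusted p under 0.05, 26 of these in the same direction, and 0 were called in both. The effect spread over all genes was 0.156 log2 units in CSS (jackknife SE 0.0324) and 0.0825 in T2D (jackknife SE 0.156), so the error of the T2D value was larger than the difference. With 6 CSS and 6 control libraries, the median over 50 draws was 53.5 calls (0 to 627, quartiles 12.3 and 175), and 3 draws gave 0. With limma voom with sample quality weights the median was 1.3e2. At the 682 genes the mean level of CSS lay nearer to that of T2D_control than the mean of CSS_control did in 81.1% (60.4% over all genes), a comparison across tables deposited apart and mice of different ages.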

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

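Tests chosen only after the result was seen were the RIN test of the length trend, the distance of the CSS groups from the T2D groups, the 70 choices of 4 controls, the removal of the length trend, the control subsets, the test between controls, the omission of 2 libraries and the striatal and thalamic covariates. For the draws of 6 against 6, for the controls with number 1 and for the striatal and thalamic covariates, how far a value had to lie beyond its bound was set stricter after the values were seen, which moved all of them from argued against to undecided.

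Of 100 splits of the 16 CSS libraries into groups of 8, the real one included, 1 gave as many as 683 calls, the real one (highest other 1). The effect spread of 0.156 was likewise reached by 1 of 100 splits (highest other 0.118). A chance division of independent mice is thus unlikely for both. The splits moved single mice, so they do not cover differences between mice that were kept or handled together, which the labels do not give. For the 10 lists called in CSS chance cannot be excluded, since 52 of 100 splits called as many (highest other 19), nor for the 11 lists in T2D (62 of 100, highest other 21) or the 7 in the contrast between cohorts (81 of 100, highest other 19). For the 0 calls by edgeR in T2D (879 at an unadjusted p under 0.05, DESeq2 4, limma voom with sample quality weights 0), 100 of 100 splits gave as many, with 14 in the highest other, which a count of 0 fixes in advance. An effect spread of 0.0825 or more came from 16 of 100 splits (highest other 0.198), so chance cannot be excluded for it. For the 12 calls of the contrast between cohorts 2 of 100 splits gave as many, the real one included. The other split gave 588 calls, far more than the real one, and how its groups overlapped the real ones was not examined. The splits thus cannot exclude chance for these 12 calls.

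In CSS long transcripts tended to be higher and short ones lower, which may come from library preparation or from the stress. With RIN as a covariate 83.9% of the 683 calls passed again in the same direction. The correlation of fold change with length was 0.26, beside 0.24 without. RIN hardly differed between the groups (9.63 ± 0.341 in CSS, 9.53 ± 0.225 in controls, exact permutation p = 0.548). Adding it could therefore hardly end the calls, so this test decides nothing about RNA integrity. CSS 5, with the steepest length slope (0.0907), had the lowest RIN of this cohort, 9. With each library's length trend taken out 45.8% passed again, between the bounds of under 1 in 3 and at least 2 in 3 set for this test. The median fold change of the 683 genes was 0.30 (SD 0.20) log2 units before and 0.27 (SD 0.21) after, and the median standard error 0.0892 and 0.0883, but why calls ended was not tested. The correlation was 0.13 against the controls with number 1 (1130 calls) and 0.32 against the others (0 calls by edgeR, 1971 at an unadjusted p under 0.05), so more calls did not go with a stronger trend there. What part of the calls the trend made, and whether it came from degradation, fragment selection or long genes that respond to stress, cannot be told apart with these libraries.

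The CSS calls depended on the controls used, and the controls, rather than the stressed mice, could be the group apart. They depended on the stressed mice too, since the lowest count on leaving out 1 library, 222, came without CSS 6. Each choice of 4 controls has fewer libraries than the full fit, which alone can lower the count. No such choices were made among the CSS libraries, so the counts cannot single out the controls. Over the 70 ways to choose 4 of the 8 controls the count ran from 0 to 1130 with a median of 12.5, 27 ways gave 0 by edgeR (against CSS_control 5 to 8, 1971 genes at an unadjusted p under 0.05), and the 4 with number 1 in their title codes gave the highest count. Against the others the called genes had 69.0% of the median fold change they had against those 4, just above a bound of 2 in 3 that would argue against these 4 making the calls, but leaving out 1 control moved the ratio between 63.0% and 72.0% (67.9% over all libraries, on log2 CPM). At 81.1% of the 682 called genes in both tables CSS lay nearer to T2D_control than CSS_control did, and at 84.6% nearer to T2D (60.4% and 63.3% over all genes), but for T2D_control 4 of 100 splits of the CSS cohort did as much at their own genes of smallest p (80.8% in the real split, highest other 84.8%; for T2D 84.8%, highest other 80.8%). The 4 controls with number 1 against the other 4 gave 11 calls (2611 genes at an unadjusted p under 0.05), so controls differed among themselves. A difference among controls in cage or handling, which the labels do not give, and a response to social stress cannot be told apart, and the T2D mice were older.

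No gene was called in T2D by edgeR (879 at an unadjusted p under 0.05, DESeq2 4, limma voom with sample quality weights 0) beside 683 in CSS (DESeq2 1313, limma voom with sample quality weights 561), which could reflect fewer libraries, more spread or a smaller response. At 6 against 6 CSS libraries the median over 50 draws was 53.5 calls, above a bound of 50 that would argue against the number of libraries as the cause, but 25 draws lay under 50 and the quartiles were 12.3 and 175, so this stays open. With limma voom the median was 1.3e2, the lower quartile 26.3 and 18 draws lay under 50. With striatal and thalamic marker scores as covariates edgeR called 0 genes in T2D (525 at an unadjusted p under 0.05) but the median standard error only went from 0.120 to 0.119, so the covariates took out little spread and dissection differences hiding the changes stay open. The biological coefficient of variation was 0.184 in T2D and 0.144 in CSS, the effect spread in T2D had a larger error than its value (0.156 beside 0.0825), and a test of the difference itself called 12 of 14888 genes. A smaller response to diabetes than to social stress was thus neither shown nor excluded.

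Single libraries stood apart from their group in 26 of 284 groups tested by Dixon's ratio, where chance flags about 1 in 20 groups, 20 of 244 among genes and 3 of 20 each among library values and marker scores. T2D 3 had 7 of these, with 46.4 CPM of Sh3bgrl2 (36.9 to 40.3 in the other T2D libraries), 23.1 of C1qc, 50.2 of Cdhr1 (2.20 to 9.14), 273 of Fam107a (172 to 195) and 12.2 of Igf1 (6.01 to 7.78), a microglia score of 0.29 and an olfactory score of 1.75. T2D 4 had 4, with 1.09 CPM of Six3 (3.89 to 5.53 in the others), 36.9 of Dcn (4.27 to 7.15), 45.6 of Nr4a2 (18.9 to 28.04) and a striatal score of −1.40. CSS 5 had 162 CPM of Igf1r, 103 of Rptor and a length slope of 0.0907 (−0.00577 to 0.0200 in the others), CSS 6 had 49.3 CPM of Hbb-bt and 11.97 of Alas2, and CSS 2 had 38.0 of Gfap and 1166 of Gapdh. CSS_control 8 had 3.83 CPM of Scarna6, 15512 of mt-Co1 and a RIN of 10, CSS_control 3 had 53.3 CPM of Csf1r, and CSS_control 2 a total of 37.5 M. T2D_control 6 had 118 CPM of Zbtb16 and 57.2 of Slc2a1, and T2D_control 3 had 109 of Insr.

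The change in CSS differed from that in T2D, by the test of the difference over all 28 libraries, for genes that include 9330159F19Rik (log2 0.49), Spred1 (0.60), Snora74a (1.12), Igsf9b (0.77), Cdh19 (0.72), Dnajc3 (0.54), Sgsm1 (0.63), C2cd2l (−0.50), Coro1b (−0.40), Sh3bgrl2 (−0.55) and Gpr12 (−0.74). With the preset correlation alone it differed for the lists of striatal (median −0.78), olfactory bulb (−0.84), inhibitory (−0.33) and excitatory neuron markers (0.14), mitochondrially encoded proteins (−0.40), immediate early genes (0.45) and heat shock and the unfolded protein response (0.27).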

How the results depend on the processing

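Alternatives chosen only after seeing the data were mixed fry, the removal of the length trend, the striatal and thalamic covariates, the number after C as a factor, the control subsets and the omission of 2 libraries. The 683 calls in CSS became 1313 with DESeq2, 349 with the length trend removed, 310 with striatal and thalamic scores, 232 without CSS 5 and CSS_control 5, 2 with the number after C as a factor, 1130 against the controls with number 1 and 0 by edgeR against those with number 2 or 3 (1971 at an unadjusted p under 0.05), and lay within 1.5 times in the other settings, with 478 under the replicate block. The 0 calls in T2D became 4 with DESeq2. The 12 calls of CSS minus T2D became 0 by edgeR with RIN, with 1 surrogate variable or with the length trend removed (1469, 1729 and 1786 at an unadjusted p under 0.05), 32 under the replicate block, 130 with DESeq2 and 45 with limma voom, and the median of 53.5 calls at 6 against 6 became 1.3e2 with limma voom. Lists called became 0 in all 3 comparisons with an estimated correlation and with directional fry, and 14 in CSS, 0 in T2D and 0 in CSS minus T2D with mixed fry. Leaving out 1 library gave 222 to 794 calls in CSS, 0 to 0 in T2D and 0 to 32 in CSS minus T2D, and 8 to 16, 7 to 16 and 2 to 7 lists. Directions turned for striatal markers in T2D with 1 surrogate variable (median 0.21, test downward), immediate early genes in T2D with RIN (0.0031) and excitatory markers in CSS minus T2D with 1 surrogate variable (−0.042). With 1 surrogate variable the medians, though not the tests, also turned for excitatory (0.0059) and oligodendrocyte precursor markers (−0.0227) in T2D. Apart from fits that left out 1 library, values of genes named for CSS kept direction and side of the threshold in 959 of 1350 cases. In 372 cases they no longer passed and in 13 they newly passed. In 6 cases the direction turned, all without a call in either fit. For T2D 370 of 384 cases kept both, 4 newly passed, and 10 turned without a call in either fit. Replicate numbers did not pair the libraries, since libraries of the same number deviated together (r over 0.1) in 3 of 8 pairs in CSS and 1 of 6 in T2D, and 2 and 0 of the pairs correlated best with their own number. Where a setting changed a count, the cause was not tested. In the fit with the number after C as a factor, CSS 6 to 8 had no control of the same number. At totals of 12.1 to 37.5 M simulated changes of 1.5-fold were recovered in 80.6% of cases in CSS and 58.2% in T2D, so smaller changes in T2D were often not detectable.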

Other observations

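Tests chosen only after the result was seen were the shares of counts from small RNAs and from 7S and 7SK RNA, the counts by gene class and gene family, the count of microglia markers by sign and the microglia level without CSS 5. Small RNA genes, which guide the chemical modification and splicing of other RNAs, were higher in CSS than in its controls. Of 27 small nucleolar RNA genes 9 rose and none fell, with a median log2 change of 0.57, and of 12 small nuclear RNA genes 5 rose and none fell, with a median of 0.63. Small nucleolar, small nuclear and Cajal body RNAs together took 0.124 ± 0.0189% of the counts in CSS and 0.0971 ± 0.0106% in controls (SD, n = 8 each, exact p = 0.00420, adjusted p = 0.0252). The share of 7S and 7SK RNA was 3.17 ± 0.744% in CSS and 2.56 ± 0.408% in controls (exact p = 0.0646, adjusted p = 0.233). In T2D the shares of the former were 0.170 ± 0.0167% and 0.165 ± 0.0321% (SD, n = 6 each, exact p = 0.766). Among 208 processed pseudogenes 1 rose and 11 fell in CSS, among 1017 long non-coding RNA genes 12 rose and 9 fell, and among 13659 protein-coding genes 285 rose and 342 fell.

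Gene families by shared symbol stem were also tested for an excess of CSS calls, 257 stems in each direction, and none passed adjustment. The Ndufa subunits of complex I came closest among falls, with 4 of 14 genes lower (adjusted p = 0.0818).

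Of the 55 genes of 5 small classes 81.8% had a positive fold change (median 0.43), 18 rose and none fell. In T2D 52.9% of 68 such genes had a positive fold change. These counts come from the genes that prompted the question and are no test of it. No test here separates stress from library preparation.

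A hypothesis is a lower share of microglial RNA in the CSS cortex. With it all 17 markers, none of them in another list, would be lower, and 1 had a positive fold change (Tmem119, 0.13), but this count is made on the list that prompted the hypothesis and is no test of it. Csf1r was at −0.23 and Ctss at −0.49. Library CSS 5 alone did not make the pattern, since without it the mean marker level was −0.24 relative to controls (SD 0.20, exact p = 0.00373) and 7 of 7 CSS libraries lay below the control mean, 5 of them below the lowest control. The size differed between markers, so a change within microglia may add to one in their number, and the list did not pass with an estimated correlation (adjusted p = 0.589). Markers were lower in T2D as well (median −0.41, adjusted p = 0.796 with an estimated correlation), and chance could not be excluded for the number of lists called in either cohort.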
